A study of Mus musculus with 6 samples.

How the data were processed

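RNA of sorted adult mouse hematopoietic stem cells was hybridised to 6 single-colour oligonucleotide arrays, 3 labelled PU.1 ki/ki and 3 wild type. Per the labels' protocols, total RNA was extracted with Trizol from the sorted cells and biotin-labelled cRNA was prepared by the manufacturer's standard procedure. The free-text description attached to each sample speaks of early embryos, which no other label does, and was set aside. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate animals or pools, nor the sex of the mice, so p-values measure only the spread between these samples, which may be technical.

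The values analysed were the intensities of the deposited series table, with 1 value per probe set and array. They were made with RMA per the submitters' processing notes, with the version not given in the sources used here. RMA values are usually on a log2 scale, whereas this table held whole numbers on a linear scale, from 10 to 27574, with 8.73 to 9.4% of probe sets at the minimum of 10. Any conversion back from the log scale and the floor are not described in the sources used here. Array medians were 41 to 46, and no further normalization was applied. Upper quartiles were 154 and 150 on wild-type replicates 2 and 3 and 180 to 188 on the others. Of 45101 table entries, 64 control probe sets were left out of the tests, which leaves 45037. No column was left unused. For arrays, the number of arrays limits the precision, and no depth applies.

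Gene names came from the platform annotation paired with the table. It gave 1 symbol for 34945 probe sets and several genes for 932, which were left unnamed, and it did not list 9160. Of the annotation's probe sets 34754 matched a mouse RefSeq gene table by gene number (assembly GRCm38.p6, used for names only), and 0 symbols were updated. For gene lists, 1 probe set per gene was kept, the one with the highest mean over the 6 arrays, which gave 18193 genes.

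All tests used log2(intensity + 1), so differences of dim probe sets are understated, and values at the floor have no order. A linear model with the genotype as its only term was fitted to every probe set with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The 28 gene lists, with 708 of 799 entries measured, were fixed before the data were examined. Each list's shift was tested with camera in limma against all other named genes, with a preset correlation of 0.01 and adjustment over the 28 lists. It was tested again with camera's estimated correlation and with the directional test of fry, which does not compare a list with other genes. Standard errors are those of the moderated fit. Spi1 was also tested with a two-sided exact permutation over 20 regroupings. Figures were drawn with matplotlib 3.10.9.

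The genes named were set by a rule written before the data were examined. It took Spi1 and, of probe sets with 1 symbol, those that passed and had no overlap between groups, up to 10 in each direction with 1 probe set per gene. It filled each direction to 10 from the largest differences at an unadjusted p under 0.01 with no overlap, passing over predicted genes. Where several probe sets of a gene qualified, the one with the largest difference was kept. It also took, in each list, the 2 higher and the 2 lower members with the lowest p, of which a part is named, and a fixed panel: E2f1, Cdk1, Cdc25a, Ccnd1, Mki67, Myc, Cdkn1a, Cdkn1b, Cdkn1c, Gfi1, Csf1r, Itgam, Cebpa, Kit, Ly6a, Slamf1, Cd48 and Xist.

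The steps were tested on simulated data. At the spread observed per probe set, 0 of 100 probe sets changed 2-fold and 0 of 100 changed 4-fold were called among 45037. At the spread of the PU.1 ki/ki arrays alone, 4 and 16 of 100 were called, and 1 unchanged probe set was. Of 28 lists shifted by 0.5 each in its own run, 27 were recovered at an unadjusted p under 0.05, and 0 lists were called with no shift. Genes were simulated as independent, so this could not show whether calls at the preset correlation are specific. In the data the estimated correlation was 0.27 for mitosis and 0.23 for DNA replication, which were not called. For the lists called at the preset it was 0.054 (interferon response), 0.018 (HSC identity), 0.024 (ribosomal proteins) and -0.027 (T and NK cell). The last is below the preset, so a higher correlation does not account for the loss of that call.

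Alternatives planned before the data were examined were a further quantile normalization, centring each array on its median, leaving out dim probe sets (mean below the median of all), a trended and robust variance prior, limma's array weights, the replicate number as a block, and each array left out in turn. For single probe sets an unmoderated test, a further limit of 1.5-fold and an adjusted p under 0.1 were added, and for lists the mean of all a gene's probe sets. Added after the data were seen were a fit without wild-type replicates 2 and 3, which leaves 1 wild-type array assumed to vary like the PU.1 ki/ki arrays, and a pseudocount of 32.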

Results

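RNA of sorted adult mouse hematopoietic stem cells (HSCs) was measured on 6 single-colour expression arrays, 3 from PU.1 knock-in homozygotes (PU.1 ki/ki) and 3 from wild-type mice. The cells had been sorted as lineage-negative, Sca1-positive, cKit-positive, CD150-positive and CD48-negative, a gate for long-term HSCs. PU.1 is an ETS transcription factor of myeloid and lymphoid development encoded by Spi1, and the title of the series concerns its autoregulation and the proliferation of adult HSCs. The comparison asked which transcripts differed between PU.1 ki/ki and wild-type HSCs, with cell cycle genes as the main interest. Values below are array intensities as mean ± SD over n = 3 arrays per group, and differences are log2 of PU.1 ki/ki over wild type.

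The wild-type arrays were less alike than the PU.1 ki/ki arrays. Pearson correlations of log2 intensities across probe sets were 0.940 to 0.951 among the PU.1 ki/ki arrays, and 0.919 to 0.926 between these and wild-type replicate 1. Wild-type replicates 2 and 3 correlated at 0.831 with each other and at 0.847 to 0.880 with the other 4 arrays. A probe set was counted as lost on an array when it lay at least 4-fold below the median of the other 5 arrays and that median was at least 512. Wild-type replicates 2 and 3 had lost 11.5% (595 of 5180) and 11.3% (590 of 5220) of such bright probe sets, wild-type replicate 1 had lost 1.12%, and the PU.1 ki/ki arrays 0.119 to 0.218%. The ratio of the 3' to the 5' Gapdh control probe set was 6.11 and 6.68 on wild-type replicates 2 and 3 and 2.98 to 4.75 on the other 4 arrays. Of the Actb control probe sets, that ratio was 0.437 on wild-type replicate 3 and 0.879 to 0.964 on the other 5 arrays. Xist, the RNA of the inactive X chromosome, was read by 3 probe sets, whose intensities on wild-type replicate 2 were 34, 24 and 16. On the brightest of these the other wild-type arrays read 6955 and 2322, and the PU.1 ki/ki arrays 4162 to 6496. Of the others, 1 read 2088 and 1250 on the other wild-type arrays and 1604 to 2027 on the PU.1 ki/ki arrays. The last read 307 on wild-type replicate 1, 18 on replicate 3, below its 24 on replicate 2, and 173 to 622 on the PU.1 ki/ki arrays. The group difference of the brightest, 3.04, had an adjusted p of 0.742 (limma) and ranged from 0.41 without wild-type replicate 2 to 4.75 without wild-type replicate 1.

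**Figure D1:**
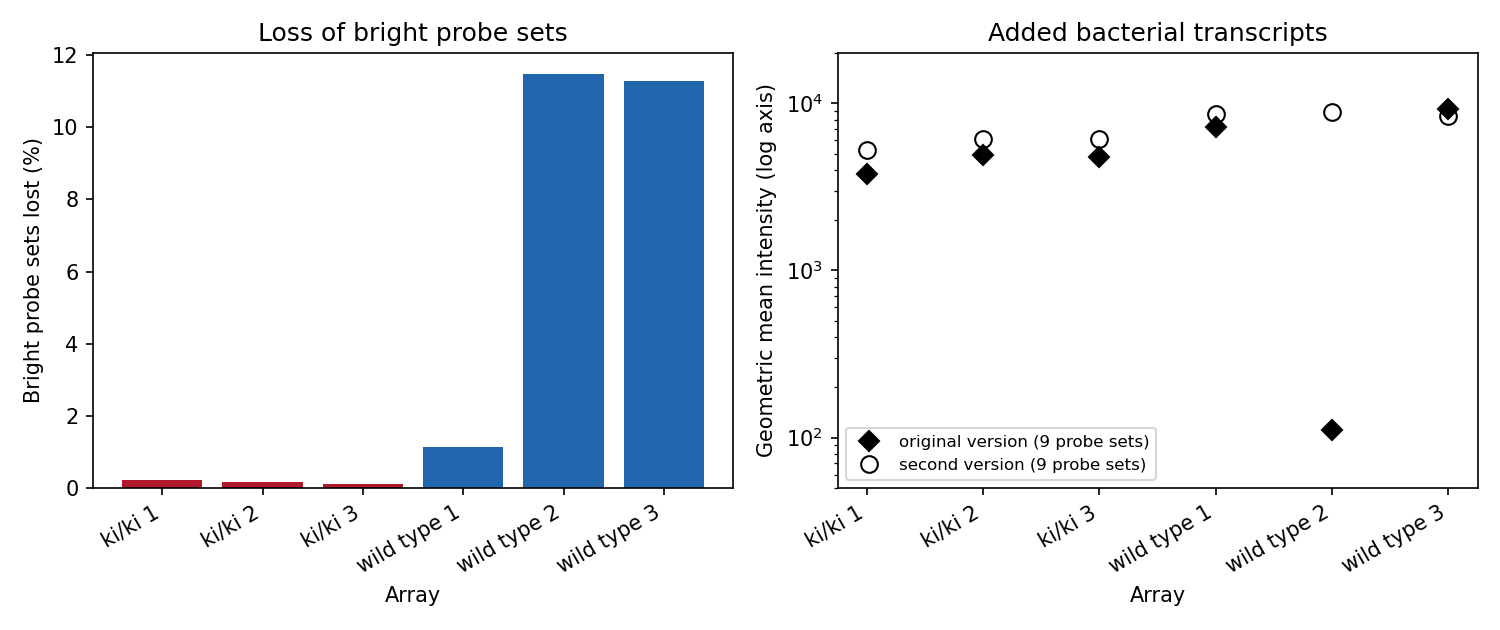
Left, percentage of bright probe sets lost on each array (bars from 0, red, PU.1 ki/ki, blue, wild type), with 11.5% and 11.3% on wild-type replicates 2 and 3. Right, geometric mean intensity (log axis) of 9 probe sets of each of the 2 design versions for bacterial transcripts added to every sample, with the original version at 110.5 on wild-type replicate 2 and at 3775 to 9269 on the other 5 arrays.

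Spi1 itself was at the same level in both groups within the spread between arrays. Its only probe set read 181 ± 27.2 in PU.1 ki/ki and 184 ± 22.6 in wild-type HSCs, a difference of -0.03 ± 0.18 (SE, 95% interval -0.48 to 0.42, limma adjusted p = 0.992). A two-sided exact permutation test gave p = 1, where the smallest p that 3 arrays against 3 allow is 0.1. The label of the arrays was therefore neither borne out nor contradicted by this transcript, since the knock-in allele's site relative to the probe set is not given in the labels.

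No probe set passed the threshold between PU.1 ki/ki and wild-type HSCs. Among the largest differences without overlap was that of Socs2, a suppressor of cytokine signalling. It read 405 ± 126 in PU.1 ki/ki against 34.7 ± 15.6 in wild type, a difference of 3.56. Its 5 other probe sets had the same sign and differed less, by 0.06 to 1.34. The brightest of these read 399 ± 202 against 171 ± 135 and overlapped between groups. Tnfrsf13c, the BAFF receptor, read 463 ± 211 against 40 ± 14 (3.47). Rp2 read 170 ± 32.8 against 17.7 ± 5.51 (3.22), with wild-type values of 14 to 24 close to the minimum of 10, so the size is uncertain. All 3 had an adjusted p of 0.4004. In the other direction, Yap1, the transcriptional effector of Hippo signalling, read 37.3 ± 11.2 against 252 ± 106 (-2.68, adjusted p = 0.419). The iron regulator Hfe read 17.7 ± 2.08 against 84.3 ± 32.02 (-2.13, adjusted p = 0.431). Its PU.1 ki/ki values, 16 to 20, were close to the minimum, so the size of this difference is uncertain. Of 45037 probe sets tested with limma, 0 had an adjusted p under 0.05 or under 0.1, and the lowest adjusted p was 0.4004. At an unadjusted p under 0.05 there were 3731 probe sets (8.28%), 2072 higher and 1659 lower in PU.1 ki/ki. An unmoderated test per probe set, over the 43874 with spread within a group, also called 0 after adjustment, with 2835 at an unadjusted p under 0.05. The balance of higher and lower in limma depended on scaling, with 1558 higher and 2243 lower after a further quantile normalization and 1593 and 2130 after centring each array on its median, which moved the median difference of all probe sets from 0.002 to -0.105. The 3 values of each group did not overlap in 5438 probe sets (12.1%, against 10% by chance), 2981 higher and 2457 lower.

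The rule for naming genes filled the lists of highest and lowest with probe sets at an unadjusted p under 0.01 whose groups did not overlap, and 0 of them passed. The 10 highest had adjusted p of 0.4004 to 0.491. Among them Mob1a, a Hippo pathway adaptor, read 1668 ± 50.2 against 191.7 ± 163 (3.61), and the endothelial adhesion receptor Adgrl4 read 1488 ± 505 against 159 ± 144 (3.53). The Schlafen family member Slfn5 read 372 ± 107 against 38.7 ± 32.5 (3.49), the ribonuclease Rnase6 212 ± 69.2 against 22.7 ± 11.02 (3.25), and Nemf, of ribosome quality control, 544 ± 254 against 68.3 ± 59.2 (3.25). Rnase6 was at the minimum of 10 on wild-type replicate 3, and its difference was 2.77 without that array. On wild-type replicates 1, 2 and 3, Mob1a read 364, 171 and 40, and Adgrl4 324, 93 and 60. Slfn5 read 76, 17 and 23 there, and Nemf 135, 48 and 22. On these probe sets replicates 2 and 3, the arrays with lost signal, thus enlarged the differences. The other probe set of Adgrl4 was lowest on replicate 1, with 35, 475 and 66 on replicates 1, 2 and 3. Its difference was 3.69. Socs2, Tnfrsf13c and Rp2 were not lowest on both replicates 2 and 3. C1qb, a chain of complement C1q, read 253 ± 273 in PU.1 ki/ki HSCs (73 to 567) and the table's minimum of 10 on all 3 wild-type arrays, so no fold is given. Igk, the symbol of the immunoglobulin kappa locus, read 2213 ± 495 against 335.7 ± 357, and its 3 other probe sets differed in the opposite direction. As a multigene family its identity is uncertain. The 10 lowest had adjusted p of 0.419 to 0.4997. Among them the flippase Atp8b4 read 29.0 ± 10 against 185 ± 138 (-2.44), the reductase Srd5a3 82.0 ± 60.5 against 385 ± 123 (-2.43), and the laminin chain Lama5 28.7 ± 9.61 against 173 ± 112 (-2.41). Tent5c read 31.0 ± 7.21 against 176 ± 94.1 (-2.36), and Tigar, a p53-responsive phosphatase, 64.3 ± 13.7 against 308 ± 130 (-2.16). Depp1 read 44.7 ± 19.1 against 190.0 ± 32.1 (-2.13), and Ubxn11 64.7 ± 33.3 against 268 ± 63.8 (-2.13). Cnn3, a calponin, was at the minimum of 10 on all 3 PU.1 ki/ki arrays and at 51.0 ± 24.3 in wild type. Other probe sets of the same gene pointed the other way for Yap1 (1 of 1), Hfe (1 of 1), Mob1a (1 of 2), Ubxn11 (1 of 2), Rp2 (1 of 4) and Srd5a3 (1 of 4). Some with the same sign differed little, for C1qb (17 against 15.7, 0.15) and Cnn3 (74.7 against 73, -0.01). The same held for a probe set of Socs2 (0.06), of Nemf (0.08), of Slfn5 (0.10) and of Tigar (-0.11). Others of the same sign differed more, as for Adgrl4 (3.69) and a further probe set of C1qb (1.30). Without wild-type replicate 1 the count at an unadjusted p under 0.05 was 7183, and without wild-type replicates 2 and 3, a choice made after the data were seen, it was 5574. In either case 0 passed adjustment.

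**Figure D2:**
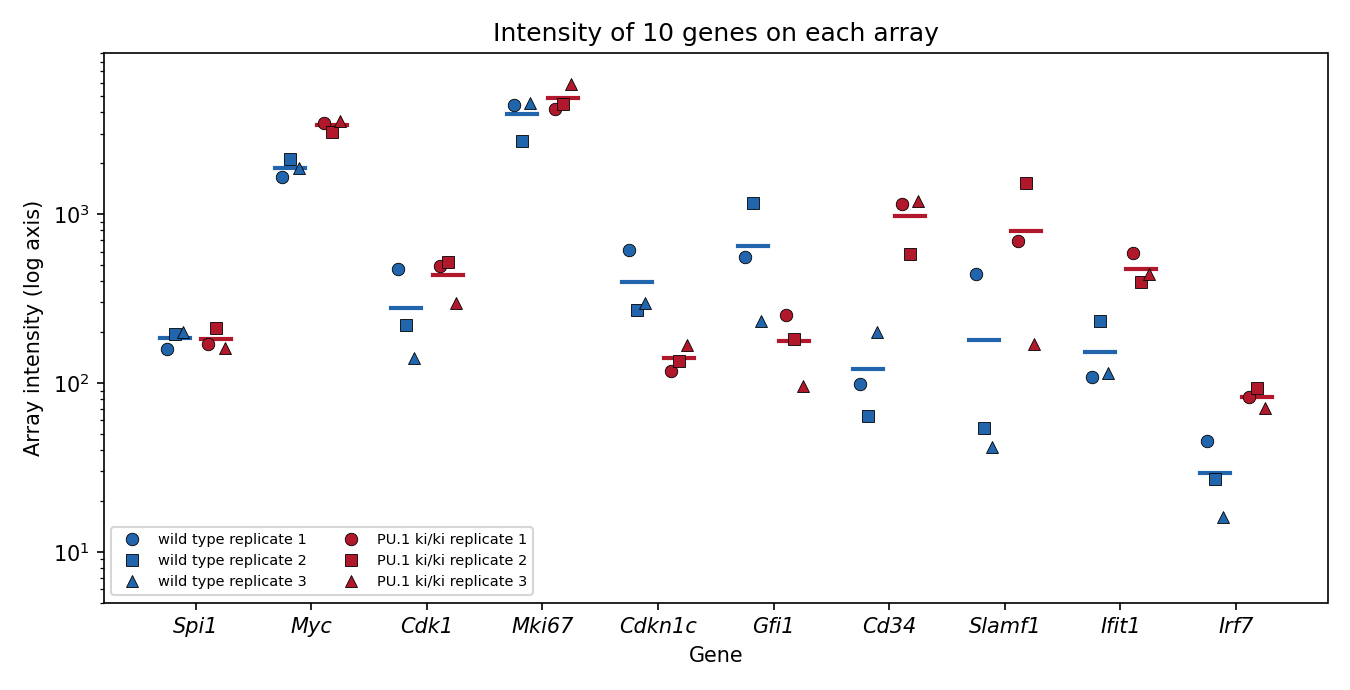
Intensity (log axis) of 10 genes on each array (blue, wild type, red, PU.1 ki/ki, marker shape gives the replicate number, and horizontal lines are group means of n = 3). Spi1 lay at 158 to 212 on all 6 arrays, and the groups did not overlap for Myc, Cdkn1c, Cd34, Ifit1 and Irf7.

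Cell cycle genes, the main interest of the design, did not differ as groups. Without overlap were 2 higher and 1 lower of 18 G1/S activators, and 1 and 1 of 40 DNA replication genes. For mitosis these were 2 and 1 of 39 genes, and for cell cycle inhibitors 1 and 1 of 19. Over all probe sets 12.1% did not overlap, against 10% by chance, so the separated members below are not evidence of a change in these lists. Myc, a driver of growth and G1 entry, read 3373 ± 253 in PU.1 ki/ki and 1883 ± 224 in wild-type HSCs (0.84 ± 0.15 SE, no overlap, adjusted p = 0.430 over all probe sets). Cdkn1c, the CDK inhibitor p57, read 140.0 ± 24.9 against 394 ± 190 (-1.40 ± 0.37, no overlap, adjusted p = 0.508), and Gfi1, a repressor that limits HSC cycling, read 177 ± 78.2 against 649 ± 472 (-1.69 ± 0.70, overlapping, adjusted p = 0.613, -2.28 to -1.12 when single arrays were left out). Of 18 measured activators of the G1/S transition 9 were higher and 9 lower in PU.1 ki/ki (median -0.03, mean 0.24, camera, with direction up, adjusted p = 0.614). Over all probe sets 0 passed, and 1, Myc, passed adjusted over the list alone. Cdc6, a licensing factor, read 754 ± 103 against 297 ± 215 (1.66, no overlap, 0.97 to 2.22 when single arrays were left out), and E2f3 read 428 ± 49.0 against 820 ± 234 (-0.90, no overlap). Cdc25a differed by 1.21 with overlap, Ccnd1 by 0.80 and E2f1 by -0.17, and when single arrays were left out these lay at 0.55 to 1.98, 0.40 to 1.22 and -1.13 to 0.55. Of the 2 other probe sets of E2f1, 1 had the opposite sign.

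For DNA replication, 30 of 40 genes were higher and 10 lower (median 0.25, camera adjusted p = 0.183). Prim1, of the primase, read 948 ± 121 against 546 ± 212 (0.85). Orc1, of the origin recognition complex, read 48.7 ± 5.77 against 123 ± 62.0 (-1.19), and its other probe set differed in the opposite direction. For mitosis, 23 of 39 genes were higher and 16 lower (median 0.17, camera adjusted p = 0.642). Random lists matched on mean intensity, drawn after the results were seen, centred on 0.16 for mitosis and 0.12 for DNA replication. These medians are therefore not to be read against 0. The mitotic kinases Aurka and Nek2 read 251 ± 71.0 against 97.7 ± 40.8 (1.39) and 195 ± 7.37 against 101 ± 37.1 (1.02), and the checkpoint kinase Ttk read 121 ± 26.5 against 292 ± 129 (-1.20). The other probe set of Aurka, that of Ttk and 1 of 3 of Nek2 had the opposite sign. Cdk1, the mitotic CDK, read 439 ± 123 against 278 ± 175 (0.79, adjusted p = 0.700) and Mki67, a proliferation antigen, 4860 ± 920 against 3890 ± 1009 (0.34, adjusted p = 0.742). When single arrays were left out, Cdk1 lay at 0.40 to 1.27 and Mki67 at 0.10 to 0.47. In both lists 0 genes passed over all probe sets and 0 adjusted over the list alone. The wild-type arrays lay on both sides of the PU.1 ki/ki arrays. The median level of the mitosis list, relative to each gene's mean, was 0.75 on wild-type replicate 1, -0.65 and -0.35 on replicates 2 and 3, and 0.00 to 0.12 on the PU.1 ki/ki arrays. Without wild-type replicate 1 the mitosis list was higher in PU.1 ki/ki (median 0.66, adjusted p = 0.0279) and so was DNA replication (0.49, adjusted p = 0.0279). Against wild-type replicate 1 alone, a setting added after the data were seen, the mitosis median was -0.62.

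Of 19 cell cycle inhibitors, 9 were higher and 10 lower (median -0.02, mean 0.26, camera adjusted p = 0.938), and 0 passed over all probe sets or adjusted over the list alone. Ccng1, a p53 target, read 1817 ± 128 against 337 ± 409 (3.16, no overlap, adjusted p = 0.519), with 809 on wild-type replicate 1 and 97 and 104 on replicates 2 and 3, the arrays with lost signal. Cdkn1a, encoding p21, read 106 ± 47.4 against 197 ± 63.5 (-0.93, adjusted p = 0.623) and Cdkn1b, encoding p27, 339 ± 38.6 against 468 ± 118 (-0.44, adjusted p = 0.654, -0.59 to -0.25 when single arrays were left out, the other probe set had the opposite sign). With 3 arrays per group, 0 of 100 probe sets changed 2-fold and 0 of 100 changed 4-fold in simulated data were called at the observed spread, and 46 and 83 of them had an unadjusted p under 0.05.

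Genes of the myeloid programme regulated by PU.1 did not differ as a group. Of 42 measured, 25 were higher and 17 lower (median 0.11, camera adjusted p = 0.802), with 0 passing over all probe sets and 0 adjusted over the list alone. Higher without passing were Lsp1, a leukocyte actin-binding protein (1076 ± 283 against 228 ± 85.7, 2.28, no overlap, adjusted p = 0.431), and the kinase Btk (226 ± 46.1 against 92.0 ± 31.95, 1.32, no overlap, adjusted p = 0.483). Lower without passing were Cebpb (134 ± 37.5 against 346 ± 130, -1.33, adjusted p = 0.509) and the Fc receptor Fcgr3 (155 ± 37.8 against 355 ± 116, -1.17, adjusted p = 0.510). Csf1r, the M-CSF receptor, read 464 ± 228 against 220.0 ± 212 (1.34, overlapping, adjusted p = 0.684, 0.90 to 2.09 when single arrays were left out). Cebpa read 82.7 ± 25.6 against 140 ± 208 (0.54, adjusted p = 0.926), with 380 on wild-type replicate 1 and 19 and 22 on replicates 2 and 3. The difference of log2 means is positive although the wild-type mean intensity is higher, because of that 1 array. Itgam was close to the minimum in both groups (16.7 ± 1.53 against 16.0 ± 4.36, 0.09). The list's median level was -0.38 on wild-type replicate 3 and -0.06 to 0.12 on the other 5 arrays, and without that array the median difference was -0.10.

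Interferon-response genes were higher in PU.1 ki/ki HSCs as a group with the preset correlation, and not with an estimated correlation or fry. Of 32 measured, 30 were higher and 2 lower, with a median difference of 0.75 (camera adjusted p = 4.5e-07, adjusted p = 0.331 with an estimated correlation, fry adjusted p = 0.086). Ifit1, an antiviral effector, read 474 ± 99.7 against 152 ± 70.8 (1.70, no overlap, adjusted p = 0.463), and Irf7, a transcription factor of the type I interferon response, 82.3 ± 11.02 against 29.3 ± 14.6 (1.57, no overlap, adjusted p = 0.508). The 2 lower members were Usp18 (72.7 ± 13.6 against 112 ± 46.2, -0.56, and -0.24 without wild-type replicate 3) and Irf9 (195 ± 55.8 against 223 ± 43.1, -0.22). No member passed over all probe sets or adjusted over the list alone. Of the members, 9 had an unadjusted p under 0.05, all higher, and 10 had no overlap between groups, against 10% by chance. The list's median level was 0.33, 0.55 and 0.57 on the PU.1 ki/ki arrays, -0.20 on wild-type replicate 1, -0.13 on replicate 2 and -0.80 on replicate 3. Against wild-type replicate 1 alone, a setting added after the data were seen, the median difference was 0.55. With 1 wild-type array, that fit holds no spread between wild-type arrays.

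Genes of HSC identity were higher as a group with the preset correlation (camera adjusted p = 0.0084) and not with an estimated correlation (adjusted p = 0.331) or fry (adjusted p = 0.181). Cd34, a sialomucin that is low on the most quiescent adult mouse HSCs, read 977 ± 342 against 121 ± 70.8 (3.09 ± 0.53 SE, no overlap, adjusted p = 0.431 over all probe sets), with 98 on wild-type replicate 1. Tek, the angiopoietin receptor, read 658 ± 117 against 318 ± 25.2 (1.04 ± 0.18, no overlap, adjusted p = 0.431), and Hoxa5 read 174 ± 103 against 425 ± 252 (-1.29, overlapping, adjusted p = 0.648), with the opposite sign on its other probe set (1.06) and a range of -1.73 to -0.84 when single arrays were left out. Of 36 measured, 25 were higher and 11 lower (median 0.44). Random lists matched on mean intensity centred on 0.13. Over all probe sets 0 passed, and 2, Cd34 and Tek, passed adjusted over the list alone. The list's median level was 0.07 to 0.37 on the PU.1 ki/ki arrays, -0.12 on wild-type replicate 1 and -0.28 and -0.40 on replicates 2 and 3. The call was also lost without wild-type replicate 3 (0.45, adjusted p = 0.0722) and with dim probe sets left out (0.37, adjusted p = 0.0972). It was lost against wild-type replicate 1 alone as well (0.37). Without PU.1 ki/ki replicate 1 the median fell to 0.23 (adjusted p = 0.0103).

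Of the markers of the sorting gate, Slamf1, encoding CD150, read 797 ± 683 against 179 ± 226 (2.48, overlapping, adjusted p = 0.655). It read 440 on wild-type replicate 1 and 54 and 42 on replicates 2 and 3. Its 2 other probe sets had the same sign and differed less (0.19 and 0.77, both overlapping). Cd48 read 203 ± 103 against 324 ± 334 (-0.26, adjusted p = 0.961) and Kit 812 ± 488 against 999 ± 624 (-0.22, adjusted p = 0.950), and both had values on either side of 0 when single arrays were left out. The other probe set of Kit had the opposite sign (0.67). Ly6a, encoding Sca1, had no probe set named by the annotation and was not analysed here. Among genes of HSC quiescence and dormancy 11 of 25 were higher and 14 lower (median -0.16, camera adjusted p = 0.601). Over all probe sets 0 passed, and 2, Tek and Cited2, passed adjusted over the list alone. Cited2, a transcriptional co-regulator, read 3568 ± 438 against 6747 ± 787 (-0.92 ± 0.16, no overlap, adjusted p = 0.431 over all probe sets). The other probe set of Cited2 had the opposite sign.

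**Figure D3:**
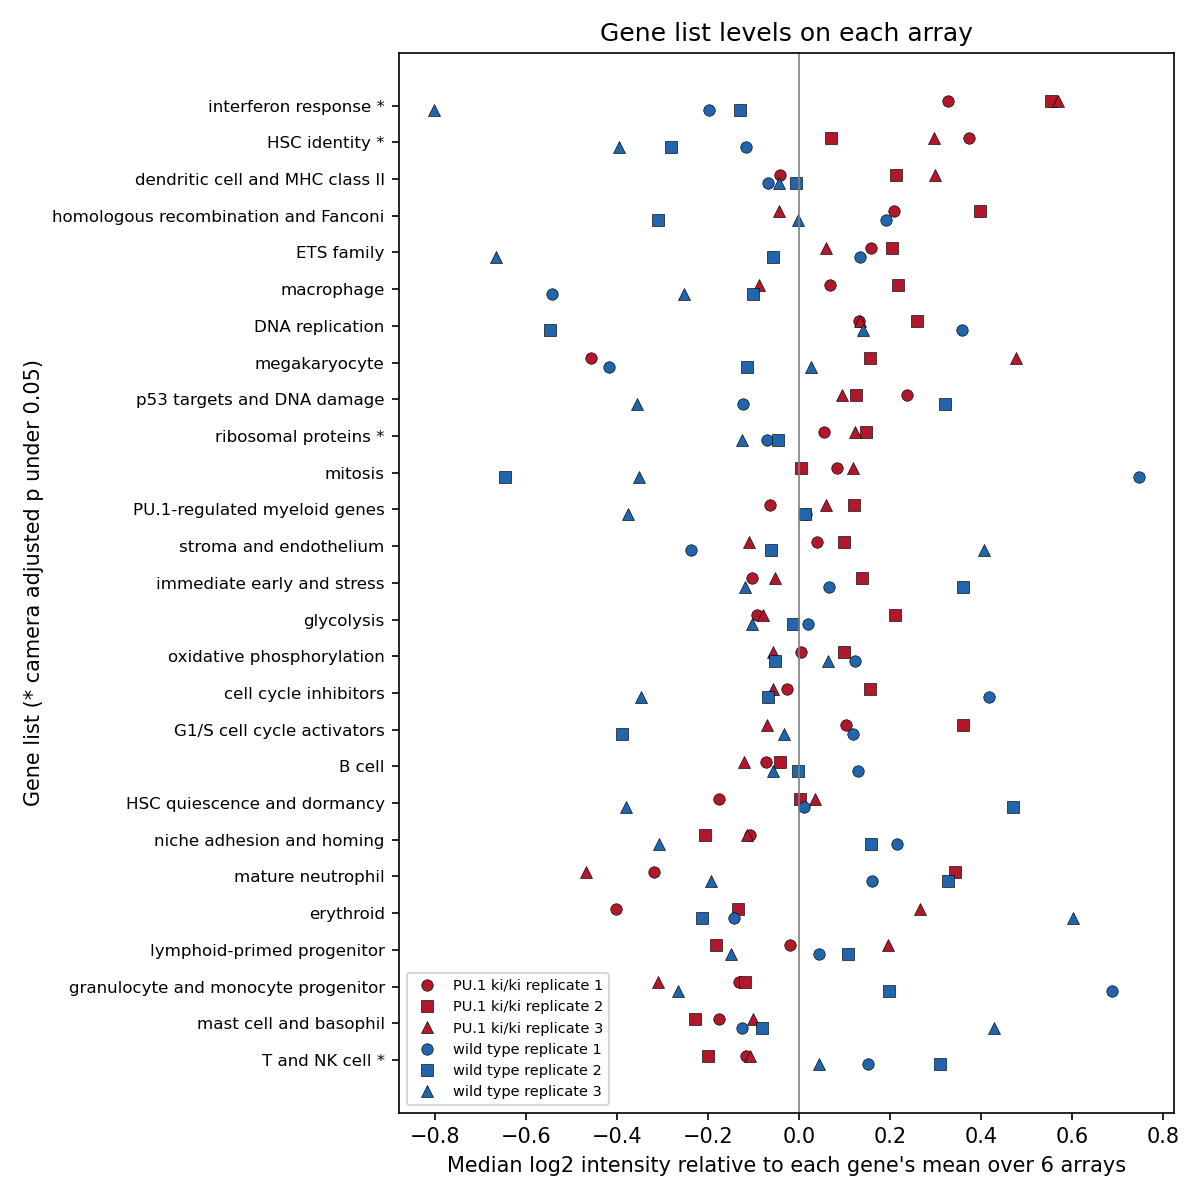
Median level of each of 27 gene lists on each array, as log2 intensity relative to each gene's mean over the 6 arrays (red, PU.1 ki/ki, blue, wild type, marker shape gives the replicate number, and an asterisk marks camera adjusted p under 0.05). The interferon list stood at 0.33 to 0.57 on the PU.1 ki/ki arrays and at -0.80 to -0.13 on the wild-type arrays.

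Ribosomal protein genes were slightly higher and T and NK cell genes lower as groups with the preset correlation, and neither was with an estimated correlation or fry. Of 44 ribosomal protein genes measured out of 78 listed, 36 were higher and 8 lower (median 0.18, camera adjusted p = 0.0087, adjusted p = 0.347 with an estimated correlation, fry adjusted p = 0.089). Rps7 read 7813 ± 667 against 5672 ± 315.5 (0.46), and its other probe set had the opposite sign. Rpl7 read 6349 ± 155 against 5203 ± 324 (0.29), and Rps28 10140 ± 109 against 11220 ± 1093 (-0.14, -0.21 to -0.073 when single arrays were left out), and each had 1 of 2 other probe sets with the opposite sign. Centring each array on its median gave 0.07 (adjusted p = 0.145). The call was also lost without PU.1 ki/ki replicate 2 (0.18, adjusted p = 0.089) and without wild-type replicate 1 (0.21, adjusted p = 0.123). Of 23 T and NK cell genes, which mark lineages the sort excludes, 6 were higher and 17 lower (median -0.41, camera adjusted p = 0.0315, adjusted p = 0.331 with an estimated correlation, fry adjusted p = 0.086). These were dim. Cd3e read 44.3 ± 13.1 against 108 ± 38.0 (-1.25), Cd5 16.7 ± 1.53 against 29.3 ± 9.07 (-0.73) and Cd4 99.0 ± 45.5 against 42.0 ± 21.2 (1.26, and 0.75 without wild-type replicate 2). The call was lost without PU.1 ki/ki replicate 1 (-0.46, adjusted p = 0.0511) or 2 (-0.33, adjusted p = 0.107), without wild-type replicate 1 (-0.37, adjusted p = 0.0508) or 2 (-0.21, adjusted p = 0.189), and with dim probe sets left out (-0.42, adjusted p = 0.249). In both lists 0 genes passed over all probe sets and 0 adjusted over the list alone.

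Markers of other blood and marrow cells were not called as groups by camera. Against random lists matched on mean intensity, drawn after the results were seen, some medians lay in the tails. With all 6 arrays these were granulocyte and monocyte progenitors (percentile 0.15), mast cells (0.37), lymphoid-primed progenitors (1.29), erythroid genes (1.58) and macrophages (98). The others lay at percentiles 3.38 to 94.48. Random lists draw genes independently, so the percentiles do not measure how unusual the medians are. Markers of granulocyte and monocyte progenitors had a median of -0.33 over 20 genes (camera adjusted p = 0.183), with Ctsg, a granule protease, at 811 ± 9.87 against 2495 ± 1132 (-1.52, no overlap, adjusted p = 0.482). Mature neutrophil markers had a median of -0.23 over 15 genes (adjusted p = 0.183), and 1 of them, Mmp9, passed adjusted over the list alone and not over all probe sets (adjusted p = 0.431). Mmp9 read 65.7 ± 18.6 against 185 ± 28.4 (-1.51, no overlap), and S100a8, abundant in neutrophils, read 2693 ± 382 against 3680 ± 435 (-0.45). Macrophage markers had a median of 0.28 over 18 genes (adjusted p = 0.183), with C1qc at 107 ± 103 against 25.7 ± 11.4. Dendritic cell and MHC class II genes had a median of 0.36 over 14 genes (adjusted p = 0.339). Cd74, the invariant chain, was at 1289 ± 137 against 445 ± 178 (1.60, no overlap, adjusted p = 0.463) and H2-Eb1 at 488 ± 86.2 against 181 ± 88.6 (1.55, no overlap, adjusted p = 0.529). Mast cell and basophil markers had a median of -0.37 over 16 genes (adjusted p = 0.174), with Mcpt8 at 25 ± 3.61 against 101 ± 69.7. Erythroid genes had a median of -0.24 over 24 genes (adjusted p = 0.783). Klf1, the erythroid regulator, read 133 ± 22.4 against 24.7 ± 15.8 (2.57, no overlap, adjusted p = 0.463), and the globin Hba-a2 4438 ± 535 against 2577 ± 506 (0.80, no overlap). Hba-a1, a globin of near-identical sequence, differed in the opposite direction, with 39.7 ± 6.35 against 66 ± 18.5 (-0.69, no overlap, adjusted p = 0.595), and 15 of the 24 genes were lower. Megakaryocyte genes had a median of 0.23 over 21 genes (adjusted p = 0.209), with Vwf at 1202 ± 338 against 468 ± 161 (1.38, no overlap, adjusted p = 0.508). Lymphoid-primed progenitor genes had a median of -0.27 over 18 genes (adjusted p = 0.614), with Cd27 at 1740 ± 209 against 871 ± 459. B cell genes had a median of -0.07 over 20 genes (adjusted p = 0.601), with Ralgps2 at 459 ± 91.7 against 185 ± 55.1, and stroma and endothelium genes 0.09 over 21 genes (adjusted p = 0.783). Over all probe sets 0 of these genes passed, and apart from Mmp9 0 passed adjusted over the list alone. The call moved past the threshold for mature neutrophil markers without PU.1 ki/ki replicate 2 (-0.55, adjusted p = 0.0079), for megakaryocyte genes without PU.1 ki/ki replicate 1 (0.49, adjusted p = 0.009) and for macrophage markers without PU.1 ki/ki replicate 3 (0.36, adjusted p = 0.0425). When single arrays were left out, the medians ranged from -0.49 to -0.075 for granulocyte and monocyte progenitors, from -0.55 to -0.078 for neutrophils, from 0.049 to 0.40 for macrophages and from 0.099 to 0.45 for dendritic cells. They ranged from -0.43 to -0.26 for mast cells, from 0.045 to 0.49 for megakaryocytes, from -0.39 to -0.0105 for lymphoid-primed progenitors and from 0.011 to 0.28 for stroma and endothelium. Against wild-type replicate 1 alone, granulocyte and monocyte progenitor markers were at -0.86.

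The remaining 8 lists did not pass either, and in these 0 genes passed over all probe sets or adjusted over the list alone. ETS family genes, the family of PU.1, had a median of 0.28 over 20 genes (camera adjusted p = 0.174), with Gabpa at 1036 ± 137 against 552 ± 211 (0.96, no overlap) and Elk3 at 834 ± 117 against 335 ± 225.5 (1.51, no overlap, 1 of 3 other probe sets opposite). Homologous recombination and Fanconi genes had a median of 0.32 over 24 genes (adjusted p = 0.174), with Exo1, a repair exonuclease, at 162 ± 45.0 against 57.7 ± 20.5 and its 2 other probe sets near 0 difference (0.0035 and -0.0096). Genes of p53 targets and DNA damage had a median of 0.23 over 22 genes (adjusted p = 0.353). Niche adhesion and homing genes had a median of -0.21 over 20 genes (adjusted p = 0.174). It became -0.44 (adjusted p = 0.0167) without wild-type replicate 3 and -0.38 against wild-type replicate 1 alone. Immediate early and stress genes had a median of 0.05, a mean of -0.10 and a camera direction of down over 28 genes (adjusted p = 0.866). The NF-kappaB inhibitor Nfkbia was at 2666 ± 411 against 1630 ± 71.6 (0.70, no overlap, 2 of 4 other probe sets opposite) and Socs3 at 18.7 ± 10.7 against 318 ± 435 (-3.11, no overlap), of which wild-type replicate 1 gave 820, and -1.90 without that array. Glycolysis genes had a median of 0.03 over 17 genes (adjusted p = 0.921). Oxidative phosphorylation genes had a median of 0.01, a mean of 0.05 and a camera direction of down over 68 genes (adjusted p = 0.810). The 4 measured sex-linked genes had a median of -0.73 and a mean of 0.01 (adjusted p = 0.424). When single arrays were left out, the medians ranged from 0.17 to 0.71 for ETS family genes, from 0.21 to 0.46 for homologous recombination and Fanconi genes, from 0.071 to 0.42 for p53 targets, from -0.44 to -0.10 for niche adhesion and from -1.06 to -0.29 for sex-linked genes. With dim probe sets left out the ETS family median was 0.83 (adjusted p = 0.0987).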

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

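The fit without wild-type replicates 2 and 3 and the pseudocount of 32 were chosen after the data were seen; all other settings were planned. The count of probe sets at adjusted p under 0.05 was 0 in every setting of limma and with the unmoderated test over 43874 probe sets. That test left out 1163 without spread in either group, of which 3, at intensities of 14 or less, differed between groups. The lowest adjusted p in limma was 0.12, without wild-type replicate 1. At an unadjusted p under 0.05 the count was 1701 (1300 higher, 401 lower) with dim probe sets left out, where 22519 were tested, 7183 without wild-type replicate 1, and 2535 to 5574 in the other settings, against 3731. No pairing by replicate number was seen, with correlations of -0.016, 0.021 and -0.017 between the deviations of same-numbered arrays. Lost signal on wild-type replicates 2 and 3 could hide a pairing, so this does not exclude it. With the replicate number as a block 0 probe sets passed, 3369 had an unadjusted p under 0.05, and no list gained or lost its call. No other Spi1 probe set is named, so that alternative gave no value. Of 81 genes named, 71 kept their sign in all settings that gave a value, and of 28 lists 15 did.

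Lost calls were as follows. With an estimated correlation and with fry, which leave the median as it is, the calls ended for interferon response (0.75), HSC identity (0.44), T and NK cell (-0.41) and ribosomal proteins (0.18). With dim probe sets left out, which leaves fewer genes, they ended for HSC identity (0.37), T and NK cell (-0.42) and ribosomal proteins (0.19, adjusted p = 0.388). Centring ended that of ribosomal proteins (0.068), and the pseudocount of 32 that of T and NK cell genes (-0.15). The interferon call held in all other settings, with a median of 0.65 to 0.95 when single arrays were left out. When single arrays were left out, HSC identity ranged from 0.23 to 0.54, T and NK cell from -0.46 to -0.21, ribosomal proteins from 0.14 to 0.21, DNA replication from -0.075 to 0.49 and mitosis from -0.12 to 0.66. The upper values of the last pair came without wild-type replicate 1, the lower ones without wild-type replicate 2. The upper ones passed only with camera at the preset correlation (adjusted p = 0.0279), which is below the correlation estimated for these lists.

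Signs also changed for values that did not pass, and the cause was not tested. When single arrays were left out, Spi1 ranged from -0.15 to 0.05 (-0.145 to 0.0525), G1/S activators from -0.11 to 0.28, cell cycle inhibitors from -0.039 to 0.28, PU.1-regulated myeloid genes from -0.10 to 0.16, HSC quiescence from -0.25 to 0.053, erythroid genes from -0.45 to 0.0088, B cell genes from -0.25 to 0.0086, immediate early genes from -0.19 to 0.090, glycolysis from -0.10 to 0.087 and oxidative phosphorylation from -0.083 to 0.017. Of single genes, E2f1 ranged from -1.13 to 0.55, Itgam from -0.15 to 0.22, Cebpa from -0.20 to 1.92, Kit from -0.81 to 0.24, Cd48 from -1.02 to 0.59 and Irf9 from -0.41 to 0.022. Quantile normalization gave -0.038 for stroma and endothelium, -0.082 for immediate early genes, -0.10 for glycolysis and -0.10 for oxidative phosphorylation. Centring gave -0.021, -0.059, -0.077 and -0.10 for these, -0.0017 for PU.1-regulated myeloid genes and -0.020 for Itgam. Leaving out dim probe sets gave 0.32 for cell cycle inhibitors and -0.019 for oxidative phosphorylation. Array weights gave 0.0088 for Spi1, 0.011 for cell cycle inhibitors and -0.027 for immediate early genes. The mean of all a gene's probe sets gave 0.075 for G1/S activators and 0.14 for HSC quiescence. Without wild-type replicates 2 and 3, mitosis was at -0.62, DNA replication at -0.15, PU.1-regulated myeloid genes at -0.24 and Spi1 at 0.18. HSC quiescence was at 0.064 there, erythroid genes at 0.17, lymphoid-primed progenitor genes at 0.037 and immediate early genes at -0.074. Glycolysis was at -0.082 and oxidative phosphorylation at -0.092. The calls of HSC identity (0.37) and T and NK cell genes (-0.18) ended there, and Cdk1 was at -0.16, Cdc25a at -0.32, Itgam at -0.18, Cebpa at -2.23, Kit at 0.95, Xist at -0.38 and Rps28 at 0.0037.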

Other observations

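All tests in the next 3 paragraphs on lost signal, the interferon list and Xist were chosen after the results were seen. The splits were set before they were run, but the interferon list was picked for them after its result.

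Many bright probe sets were lost on wild-type replicates 2 and 3, and lower RNA of those genes as the whole cause is argued against by other probe sets of the same genes. Over 6014 named probe sets at 256 or above on each of the other 4 arrays, 721 and 735 were lost on replicates 2 and 3, with 191 lost on both against 88.1 expected if independent. The other bright probe sets of the same genes deviated by a median of -0.23 on replicate 2 (95% bootstrap interval -0.33 to -0.17, 620 probe sets) and by -0.22 on replicate 3 (-0.29 to -0.15, 562 probe sets), close to the median of all bright probe sets (-0.24 and -0.26), although 24.4% and 24.0% of them lay at -1 or below. That share was not taken for all bright probe sets. The lost ones were picked on the same arrays, so others of their genes would lie nearer the median to some degree anyway. The high Gapdh ratios of these arrays (6.11 and 6.68) were not taken into account. On replicate 2, 9 of 9 probe sets of the original design version for added bacterial transcripts were lost and 0 of 9 of the second version for the same transcripts, so a loss of signal on the array or in its processing may account for at least part there. On replicate 3, 0 of 9 were lost, which leaves open how its signal was lost.

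Interferon-response genes were higher in PU.1 ki/ki HSCs with camera at the preset correlation, and not with an estimated correlation (adjusted p = 0.331) or fry (adjusted p = 0.086), and 2 technical explanations were tested. If the lost signal of wild-type replicates 2 and 3 were the cause, the list would not stand out against wild-type replicate 1 alone, where 26 of 32 genes were higher and the median of 0.55 lay at percentile 99.9 of 10000 random lists matched on mean intensity. That comparison is not specific, since 10 of the 28 lists lay outside the central 95% of their matched lists there, and 11 with all 6 arrays. The 11 included lists that camera did not call, such as granulocyte and monocyte progenitors. With all 6 arrays the lists of the same brightness centred on 0.12, against 0.75 for the interferon list (percentile 100). Brightness alone thus falls short of the shift. The interferon list was picked after its result and the random lists draw genes independently, so the percentile does not measure how unusual the shift is. The genotype, and differences between the animals that the labels do not describe, may each account for the shift and remain untested.

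All 3 Xist probe sets were near the floor on wild-type replicate 2, and 1 of them also on replicate 3, while Y-linked probe sets were raised there. Kdm5d read 334, 118 and 59 on that array and 10 to 24 on the other 5, Eif2s3y 75 and 112 against 10 to 28, and a probe set of Uty 86 against 10. Of 9 Y-linked probe sets under 40 on the other 5 arrays, 6 were at least 2-fold above the highest of them, against 2.81% of 14283 other such probe sets (two-sided Fisher's exact test, p = 4.0e-08). The 9 all belong to Kdm5d, Eif2s3y and Uty. Probe sets of a gene are not independent, so this p is too small. The raised Y-linked signal argues against lost signal as the whole cause, and RNA of a male animal in that sample may account for it. The sex of the mice is not given in the labels, and no probe set of Ddx3y was named.

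Other splits of the arrays were counted for the tests over all probe sets. In 10 of the 10 splits 0 probe sets passed the adjusted threshold, so as many as in the real one. The real split gave 3731 probe sets at an unadjusted p under 0.05, the highest other 3016, and 1 of 10 splits gave as many. By camera, 4 lists were called in the real split and 4 in the highest other, and 3 of 10 splits gave as many. The interferon median lay as far from 0 in 1 of 10 splits, the real one (0.75, with 0.53 as the highest other). Camera also called the list in 2 of the 9 other splits (0.48, adjusted p = 0.0033, and 0.53, adjusted p = 0.0032). The 10 splits are too few for a share under 0.05.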
